A study of Homo sapiens with 6 samples.

How the data were processed

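Poly(A) RNA of cells labelled OVCAR3 was sequenced in 6 libraries, 2 with a non-targeting hairpin and 2 with each of 2 hairpins against HNRNPL. The deposited values are counts, 1 file per library, of reads per Ensembl gene, and the authors applied no normalisation to them. The submitters' processing notes name cutadapt 1.18, TopHat2 2.1.1 and HTSeq with the hg38 genome; HTSeq's version, its strand setting and the annotation release are not given in the sources used here. The last 5 lines of each file, which give reads assigned to no gene, were kept out of the tests and used as library measures. Reads in genes made up between 40.9% and 43.5% of all counts in a file, reads in no gene between 42.5% and 46.5%, ambiguous reads between 2.24% and 2.53% and reads with more than 1 alignment between 7.67% and 13.7%.

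The files hold 60715 genes. A symbol was found for 42058 of them, and 58497 had an entry in GENCODE release 29, as did 98.4% of the tested genes. Positions, gene types, GC content and overlaps came from that release. Counts were filtered with edgeR's filterByExpr, which left 17888 genes, normalised by TMM with factors between 0.970 and 1.04, and fitted with edgeR 4.0.16 in R 4.3.3 using glmQLFit without robust estimation and glmQLFTest. The model held the 3 groups and all 6 libraries, with 3 residual degrees of freedom, 11.1 prior degrees of freedom and a biological coefficient of variation of 9.16%. Contrasts were the mean of sh1 and sh2 against control, each hairpin against control, and sh1 against sh2. Tests were 2-sided, p-values were adjusted over all tested genes by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of its F statistic. Levels are given as normalised CPM with the SD of 2 libraries, except that levels of cell type markers in the controls are mean CPM without the TMM factor and without an SD. The limit of 3 counts covers counting error only. Intervals of shares are binomial, those of list ratios and of overlapping pairs come from resampling genes or pairs, and that of an SD from the chi-square distribution.

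The tests, the gene lists, the naming of genes and the first set of alternatives were fixed before the data were examined. HNRNPL, HNRNPLL and PIK3CB were always named. The other named genes were the 12 largest rises and the 12 largest falls in the average contrast that were also called in the same direction with each hairpin, the 5 largest in each direction for each hairpin, and the 8 largest in each direction between hairpins. Each had a mean of at least 5 CPM and a symbol that is not a clone, LINC, small RNA or pseudogene name. Some genes that this rule or a list holds are not reported here. For a list, up to 4 members with the smallest p were named; members named beyond these were chosen after their values were seen.

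The 27 lists covered glycolysis, PI3K-AKT signalling, hnRNP proteins, SR splicing proteins, nonsense-mediated decay, G1/S and DNA replication, G2/M and mitosis, p53 targets, interferon-stimulated genes, NF-kB and cytokines, the unfolded protein and integrated stress response, heat shock, immediate early genes, hypoxia beyond glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, the tricarboxylic acid cycle, cholesterol synthesis, cytosolic ribosomal proteins, replication-dependent histones, apoptosis regulators, and markers of ovarian carcinoma, epithelium, mesenchyme, fibroblasts, leukocytes and endothelium. Each was tested with limma 3.58.1's camera on log-CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 27 lists of a contrast. Members called are given over all genes and adjusted over the list alone. The correlation was also estimated from the data, and fry was run as a self-contained test.

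Alternatives were DESeq2's size factors, no low-count filter, a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, glmTreat against a fold of 1.5, the replicate number as a block, each library left out in turn, only the groups compared, and the 4 knockdown libraries as 1 group. After the data were seen, fits were added without genes overlapping an opposite-strand gene, over 13148 coding genes with and without a correction of each library for GC content and length by splines with 4 degrees of freedom, and with the controls divided between the hairpins, which leaves 2 residual degrees of freedom and assumes that a lone control varies like the other groups. Calls were also counted without genes found to carry words tied to a hairpin. The words came from a scan of all 7-base words in annotated 3′ untranslated regions against the log2 difference between hairpins. The pipeline was tested on simulated data with 200 changed genes, where it recovered 96% of changes of 1 log2 unit and 100% of changes of 2 in the average contrast, with 11 false calls among 207. With sh1 it recovered 93% and 100%, with 16 false calls among 209, with sh2 93% and 100%, with 9 among 202, and between hairpins, where no gene was changed, it made 2 calls. For the shared controls, 30 sets of unchanged groups were simulated. Other steps used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.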

Results

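RNA was sequenced in 6 libraries to ask which transcripts respond to loss of hnRNPL, an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein family. The labels name the cells OVCAR3, an established human ovarian carcinoma line, and give the cell type as fibroblasts. The series title links hnRNPL to transcription of PIK3CB and to glycolysis. There were 2 control libraries with a non-targeting hairpin and 2 libraries with each of 2 hairpins against HNRNPL, called sh1 and sh2. Counts in genes were 13619962 and 13336563 in control 1 and control 2, 13160092 and 12278260 in sh1 1 and sh1 2, and 13202619 and 12650353 in sh2 1 and sh2 2. A count of 0 therefore allowed between 0.220 and 0.244 CPM (counts scaled to library size), taking 3 counts as the upper limit. Log-CPM profiles correlated at 0.991 within the controls, 0.985 within sh1 and 0.990 within sh2, across genes, which are not independent replicates. The sh1 pair was the least alike, with a count spread of 10.5 times the Poisson variance against 3.12 in the controls and 3.71 in sh2. Mitochondrially encoded genes took between 2.60% and 3.12% of counts. The labels do not say that the replicates were separate cultures, so every p-value measures the spread between these libraries.

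HNRNPL RNA fell with both hairpins. HNRNPL (ENSG00000104824.17, hg38 chromosome 19, 38836388 to 38852347) stood at 180.3 ± 0.920 CPM in the controls (SD, n = 2), 27.4 ± 1.21 in sh1 and 35.8 ± 5.59 in sh2. These levels were 15.2% and 19.8% of control. The log2 fold change was -2.72 (SE 0.124) with sh1 and -2.33 (SE 0.121) with sh2, with edgeR quasi-likelihood adjusted p of 3.3e-08 and 1.6e-07. The hairpins differed in HNRNPL by -0.39, adjusted p = 0.0532, which did not pass. That difference ranged from -0.53 without sh2 1 (adjusted p = 0.0697) to -0.22 without sh2 2 (0.469), and it passed without sh1 2 (0.0392), by DESeq2 (0.0483) and with no low-count filter (0.0314). HNRNPLL, the close paralog of HNRNPL (chromosome 2, 38561978 to 38603586), rose from 37.8 ± 2.26 CPM to 50.9 ± 4.73 in sh1 and 47.7 ± 3.63 in sh2. Its average log2 fold change was 0.38 (SE 0.106), edgeR adjusted p = 0.0209, with 0.0227 for sh1 and 0.0694 for sh2 alone. HNRNPLL did not pass without control 1 (adjusted p = 0.268), control 2 (0.105) or sh2 1 (0.103), nor against a fold of 1.5 (adjusted p = 1). With sh1 alone it did not pass without control 1 (adjusted p = 0.233), control 2 (0.0888) or sh1 2 (0.0562), and with sh2 alone it passed without sh1 1 (0.0123) or sh1 2 (0.0182). AC008982.1, a coding gene on the same strand, overlaps HNRNPL, and reads shared by both were set aside as ambiguous.

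**Figure D1:**
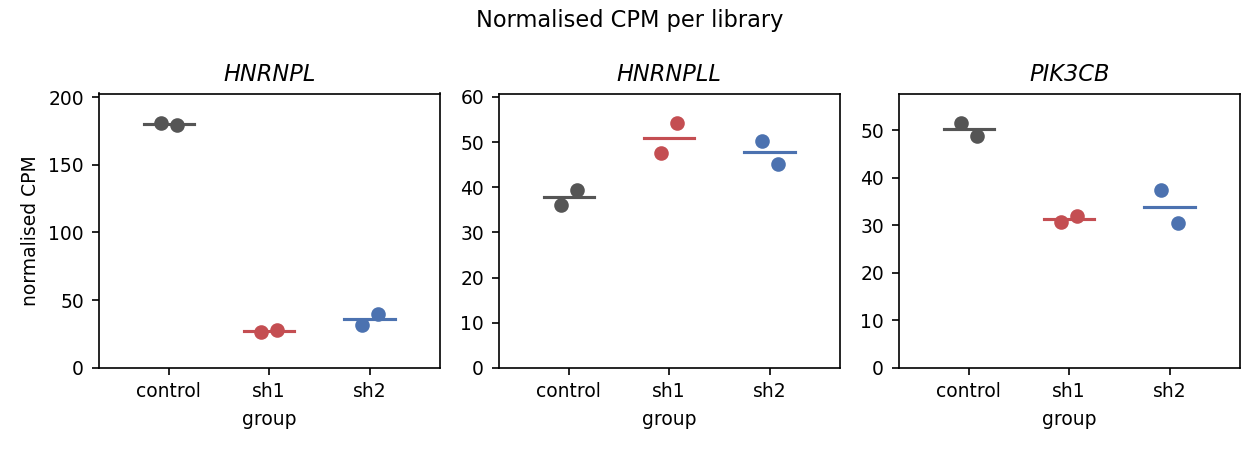
Normalised CPM of HNRNPL, HNRNPLL and PIK3CB in each library, by group; points are libraries and lines are group means. HNRNPL stood at 15.2% of control with sh1 and 19.8% with sh2, and PIK3CB at 62.4% and 67.5%.

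PIK3CB, which encodes the p110-beta catalytic subunit of PI3-kinase and is the gene named in the series title, fell with both hairpins. PIK3CB (chromosome 3, 138652699 to 138834938) stood at 50.2 ± 1.93 CPM in the controls (SD, n = 2), 31.3 ± 0.816 in sh1 and 33.9 ± 4.97 in sh2, or 62.4% and 67.5% of control. The log2 fold change was -0.62 (SE 0.106) on average, -0.68 (SE 0.125) with sh1 and -0.57 (SE 0.125) with sh2. The edgeR adjusted p values were 0.00111, 0.00202 and 0.00706, and the hairpins differed by -0.11 (adjusted p = 0.595). Tested against a fold of 1.5 in place of no change, PIK3CB did not pass (adjusted p = 1). With sh2 alone, PIK3CB did not pass without control 1 (adjusted p = 0.0861) or sh2 2 (0.125). The 3′ untranslated region of PIK3CB carries a 7-base word tied to lower RNA with sh1 than with sh2, as do 36.6% of the scanned genes. It carries none tied to lower RNA with sh2 than with sh1. Whether the word plays a part in the fall of PIK3CB was not tested.

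Of the 28 measured PI3K-AKT signalling genes, none rose and 8 fell in the average of both hairpins (adjusted over the list alone, 1 higher and 10 lower). IRS1, an insulin receptor substrate, fell by 0.87 (SE 0.116) on the log2 scale, and INPP4B, a phosphoinositide phosphatase, by 0.62 (SE 0.0991). The list had a median of -0.10 and did not pass camera's test, adjusted p = 0.0743. With an estimated correlation the adjusted p was 0.696. With 1 library left out, the median ranged from -0.16 (without sh1 2) to -0.08 (without sh2 2). With sh2 alone the list passed, at adjusted p = 0.0223 and a median of -0.19 (adjusted p = 0.611 with an estimated correlation), while sh1 gave 0.335, and the difference between hairpins gave 0.601. PIK3R1, a regulatory subunit of PI3-kinase, fell by 0.99 (SE 0.180) with sh2 and had a log2 fold change of 0.12 with sh1. The average test passed without control 2 (adjusted p = 0.0353), sh1 2 (0.0162) or sh2 1 (0.0423) and with no low-count filter (0.00572). Over coding genes corrected for GC content and length, the average median moved from -0.09 to -0.01, with 6 members higher and 9 lower. With sh2, the median moved from -0.19 to -0.04, and the members called from 0 higher and 8 lower to 3 higher and 7 lower.

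Glycolysis genes moved in both directions, with 4 of 25 higher and 2 lower on average (adjusted over the list alone, 4 higher and 2 lower). LDHA, the lactate dehydrogenase subunit that makes lactate, rose by 1.24 (SE 0.0912), and HK1, a hexokinase, by 0.80 (SE 0.0865). SLC16A1, a lactate transporter, fell by 0.61 (SE 0.0874), and PFKFB4, which sets the level of an activator of phosphofructokinase, by 0.68 (SE 0.0976). PDK1 and TPI1 also rose, by 0.52 (SE 0.146) and 0.28 (SE 0.0840). PFKM, the muscle-type phosphofructokinase, went opposite ways with the hairpins, at 0.54 with sh1 and -0.42 with sh2. Of these, average calls were lost for PDK1 (adjusted p = 0.231) and TPI1 (0.232) without control 1, PDK1 (0.0958) and TPI1 (0.252) without control 2, PDK1 (0.0726) and TPI1 (0.129) without sh2 1, and PDK1 (0.0652) and TPI1 (0.114) without sh2 2. With sh2, PFKM did not pass without control 1 (adjusted p = 0.122), control 2 (0.0965), sh2 1 (0.145) or sh2 2 (0.0816). The list's median was 0.04 and camera's adjusted p was 0.339, or 0.705 with an estimated correlation. With 1 library left out, the median ranged from 0.00069 (without control 2) to 0.047 (without control 1). The self-contained test fry, which asks whether the members moved on balance one way, gave adjusted p = 0.0461 (up), and its mixed form, which allows either direction, gave 8.9e-05. Over coding genes corrected for GC content and length, the average median moved from 0.05 to 0.09, with 7 members higher and 2 lower. Reads of ALDOA and LDHB were scarce, with means of 2.43 and 1.35 CPM, and both genes overlap a coding gene on the same strand, as PFKFB4 does, so their values are uncertain.

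**Figure D2:**
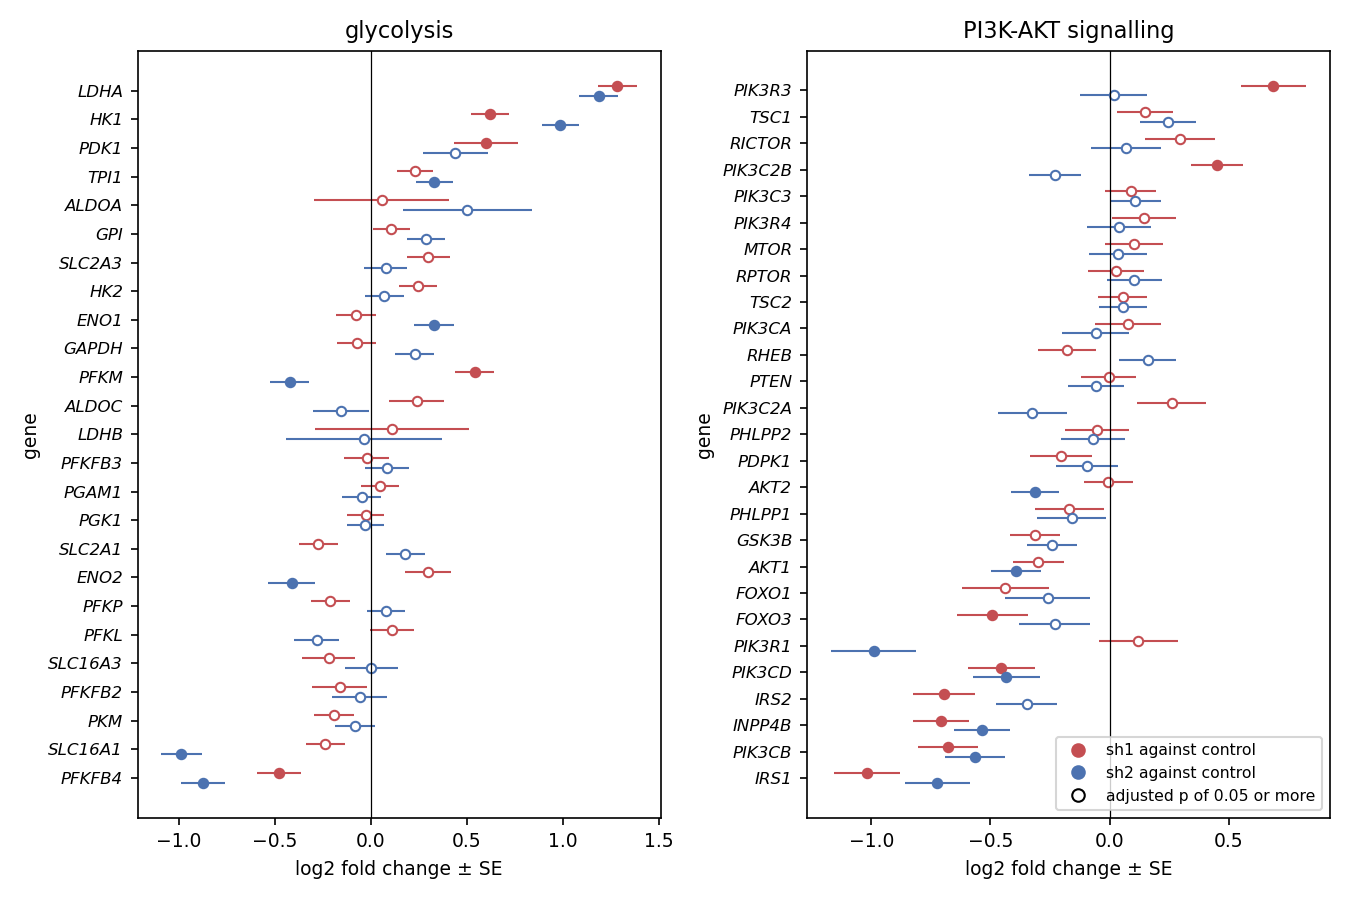
Log2 fold change with its SE for the 25 measured glycolysis genes and 27 of the 28 measured PI3K-AKT signalling genes, in sh1 and in sh2 against control; filled points passed at an adjusted p of 0.05. LDHA and HK1 rose and PFKFB4 fell with both hairpins, and PIK3CB, IRS1 and INPP4B fell with both.

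In the average of both hairpins, FBXW10B, an F-box gene, rose by 2.25 (SE 0.220) on the log2 scale, USP18, a protease that removes the ubiquitin-like protein ISG15, by 1.90 (SE 0.126), and VAV3, a signalling gene, by 1.69 (SE 0.127). LIMA1, an actin-binding protein gene with far more counts, went from 109.5 ± 1.95 CPM to 284 ± 9.74 in sh1 and 377 ± 24.6 in sh2 (SD, n = 2). Also higher were the F-box gene FBXO10 (1.53), ARHGAP19 (1.47), the dehydratase gene L3HYPDH (1.40), the neuropeptide receptor gene NPFFR2 (1.39) and CETN3 (1.34), a centriole component. Non-coding transcripts among them were MRPS30-DT (2.16), TMEM161B-DT (1.65) and LUCAT1 (1.52). Adjusted p for these genes ranged up to 3.6e-04 (edgeR, NPFFR2). USP18 has a near-identical copy, USP41, and FBXW10B has the paralog FBXW10, so reads could not be assigned between the copies with certainty. TMEM161B-DT lies opposite TMEM161B, which has more counts, and FBXW10B, ARHGAP19, FBXO10 and L3HYPDH overlap a coding gene on the same strand.

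Besides HNRNPL, the genes that fell furthest in the average of both hairpins included LTBP2 and MMP9. LTBP2, an extracellular matrix protein, had a log2 fold change of -1.97 (SE 0.130), and the matrix metalloproteinases MMP9 and MMP1 had -1.87 (SE 0.123) and -1.83 (SE 0.202). The cytokine genes CSF2 and TNFSF15 had -1.94 (SE 0.225) and -1.88 (SE 0.185). CHAC1, an enzyme that breaks down glutathione, had -1.96 (SE 0.197), the protease inhibitor CST1 -1.74, the protocadherin PCDH1 -1.73, the lipoprotein lipase inhibitor ANGPTL4 -1.69 and the follistatin-like FSTL4 -1.69. Adjusted p for these genes ranged up to 1.0e-04 (edgeR, CST1). RAB11B-AS1, on the opposite strand, has more counts than ANGPTL4.

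Among gene lists, 4 were higher in the average of both hairpins. Interferon-stimulated genes had 11 of 29 members higher and none lower (adjusted over the list alone, 12 higher and 0 lower), with camera's adjusted p = 4.8e-06 (adjusted p = 0.371 with an estimated correlation). Among them were IFIT2 (0.86, SE 0.0878), RSAD2 (0.71, SE 0.0882), both antiviral effectors, and XAF1 (0.92, SE 0.140). Replication-dependent histone genes, whose RNAs mostly lack a poly(A) tail and were read here in poly(A) libraries, had 9 of 20 higher and none lower (adjusted over the list alone, 11 higher and 0 lower), including H2AC8 (1.04, SE 0.141) and H2BC5 (0.64, SE 0.124). Camera gave them adjusted p = 5.4e-05 (adjusted p = 0.371 with an estimated correlation). G2/M and mitosis genes had 10 of 24 higher and 1 lower (adjusted over the list alone, 13 higher and 1 lower), with adjusted p = 1.5e-04 (adjusted p = 0.371 with an estimated correlation). The mitotic kinesin KIF20A stood at 0.86 (SE 0.0916), HMMR at 0.95 (SE 0.115) and the survivin gene BIRC5 at 0.60 (SE 0.107), while the phosphatase gene CDC25B fell by 0.36 (SE 0.0834). Cytosolic ribosomal protein genes had a median of 0.12 with only RPLP0 (0.55, SE 0.0902) called of 31 (adjusted over the list alone, 1 higher and 0 lower), and adjusted p = 0.0315 (adjusted p = 0.737 with an estimated correlation). The ribosomal list did not pass without control 2 (adjusted p = 0.237), sh1 1 (0.569) or sh2 2 (0.127), nor with no low-count filter (0.0734) or with fry (0.595). Its median was 0.0028 without sh1 1, 0.08 without control 2 and 0.20 without sh1 2, and moved from 0.14 to 0.07 over coding genes corrected for GC content and length. Among the members named, calls were lost for H2BC5 (adjusted p = 0.0611), BIRC5 (0.0502) and CDC25B (0.172) without control 1, and CDC25B (0.0830) without control 2. Of these 4 lists, G2/M and mitosis passed with sh1, at adjusted p = 0.00110 (adjusted p = 0.697 with an estimated correlation), and with sh2, at adjusted p = 5.5e-04 (adjusted p = 0.515 with an estimated correlation). Interferon-stimulated genes did not pass with sh2 (adjusted p = 0.200, median 0.06). With sh1, histone genes (adjusted p = 0.314) and ribosomal protein genes (adjusted p = 0.965, median -0.01) did not pass.

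Another 6 lists were lower. Of 24 cholesterol synthesis genes, 11 were lower and none higher (adjusted over the list alone, 1 higher and 16 lower), with camera's adjusted p = 1.5e-04 (adjusted p = 0.371 with an estimated correlation). The desaturase SC5D stood at -0.97 (SE 0.0997) and the oxidase MSMO1 at -0.81 (SE 0.0914). Of 21 p53 targets, 9 were lower and none higher (adjusted over the list alone, 0 higher and 9 lower), with adjusted p = 2.4e-04 (adjusted p = 0.371 with an estimated correlation). They included the cell-cycle inhibitor CDKN1A at -0.99 (SE 0.0960), SESN2 at -1.35 (SE 0.103) and GDF15 at -1.20 (SE 0.144). Unfolded protein and integrated stress response genes had 10 of 24 lower and none higher (adjusted over the list alone, 0 higher and 12 lower), with adjusted p = 2.0e-04 (adjusted p = 0.560 with an estimated correlation). Beside CHAC1 and SESN2, the serine synthesis genes PSAT1 and PHGDH stood at -0.87 (SE 0.0912) and -0.84 (SE 0.0932). Epithelial junction and keratin genes had 11 of 20 lower and none higher (adjusted over the list alone, 0 higher and 11 lower), with adjusted p = 0.00117 (adjusted p = 0.371 with an estimated correlation). KRT7 stood at -1.01 (SE 0.0834), the claudin CLDN1 at -1.22 (SE 0.114) and KRT19 at -1.07 (SE 0.106); KRT7 overlaps another keratin gene on the same strand.

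Mesenchymal and EMT factors had 7 of 19 members lower and none higher (adjusted over the list alone, 0 higher and 8 lower), with camera's adjusted p = 0.0260 (adjusted p = 0.646 with an estimated correlation). They included the actin-binding TAGLN (-1.61, SE 0.136), the integrin ITGB1 (-0.74, SE 0.0891) and the matrix glycoprotein THBS1 (-0.66, SE 0.0927). Fibroblast markers had 3 of 13 lower and 1 higher (adjusted over the list alone, 1 higher and 8 lower), with adjusted p = 0.0479 (adjusted p = 0.371 with an estimated correlation). The fibrillin FBN1 stood at -1.33 (SE 0.124) and COL6A1 at -0.68 (SE 0.101), against COL1A1 at 0.42 (SE 0.0962), and COL6A3, at 2.71 CPM in the controls, also fell. The call of COL1A1 was lost without control 1 (adjusted p = 0.133) or control 2 (0.0985). Of the 6 lower lists, p53 targets (adjusted p = 0.209) and fibroblast markers (adjusted p = 0.314) did not pass with sh1, and mesenchymal factors (adjusted p = 0.249) did not pass with sh2. The mesenchymal list did not pass without control 1 (adjusted p = 0.0984) or sh1 1 (0.0510), and the fibroblast list did not pass without control 1 (0.0712) or sh2 2 (0.0750) or at a filter of 5 CPM (0.138). The mesenchymal median of -0.17 was -0.08 without control 1 and -0.28 without control 2. All 10 lists kept the sign of their median after correction for GC content and length, and camera with an estimated correlation called 0 of the 27, with 2 at an unadjusted p under 0.05. Fry called 13 lists.

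By edgeR's quasi-likelihood test, 3420 of 17888 genes were called in the average of both hairpins against control at an adjusted p under 0.05, 1316 higher and 2104 lower, and 267 and 322 of these by more than 2-fold. Coding genes made up 1003 of the higher and 1843 of the lower genes, and other gene types 313 and 261. Over coding genes with a GC value, 39.2% of 3013 called genes were higher, against 48.3% of 4016 after correction for GC content and length. The count was 1037 without control 1, 1327 without control 2, 5249 without sh1 2, 1969 without sh2 1 and 2273 without sh2 2. It was 246 against a fold of 1.5, 758 with the 4 knockdown libraries as 1 group, 1993 without genes overlapping an opposite-strand gene and 2059 without genes carrying a hairpin's 3′ words.

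With sh1 alone, MRPS30-DT (2.49, SE 0.238), FBXW10B (2.21, SE 0.242), TMEM161B-DT (2.06, SE 0.246), VAV3 (2.05, SE 0.139) and USP18 (1.99, SE 0.137) rose furthest. HNRNPL, CSF2 (-2.55, SE 0.292), CHAC1 (-2.45, SE 0.252) and the caveolin CAV2 (-2.28, SE 0.120) were among those that fell furthest. Interferon-stimulated genes had 17 of 29 higher and none lower (adjusted over the list alone, 22 higher and 0 lower), with camera's adjusted p = 1.5e-10 (adjusted p = 0.402 with an estimated correlation). DNA replication genes had 3 of 24 higher (adjusted over the list alone, 5 higher and 1 lower), led by CDC45 (0.62, SE 0.126) and CLSPN (0.48, SE 0.113), with adjusted p = 0.0192 (adjusted p = 0.770 with an estimated correlation). With sh1, calls were lost for CDC45 (adjusted p = 0.0883) and CLSPN (0.0714) without control 1, and CLSPN (0.112) without control 2. Of 27 lists, 7 passed with sh1, 3 higher and 4 lower; 0 passed with an estimated correlation (1 at an unadjusted p under 0.05) and 13 with fry. In all, edgeR called 3376 genes, 1385 higher and 1991 lower. Over coding genes alone, 41.8% of 2916 called genes were higher, against 48.3% of 3897 after correction for GC content and length. The count was 1210 without control 1 and 1577 without control 2, 344 against a fold of 1.5, 2063 without genes overlapping an opposite-strand gene and 2011 without genes carrying the 3′ words.

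With sh2 alone, FBXW10B (2.28, SE 0.241), MRPS30-DT (1.82, SE 0.249), USP18 (1.81, SE 0.138), LIMA1 (1.78, SE 0.102) and PSG4 (1.64, SE 0.170), a member of the pregnancy-specific glycoprotein family whose near-identical copies make its value uncertain, rose furthest. The fucosyltransferase FUT8 (-2.63, SE 0.138), HNRNPL, LTBP2 (-2.29, SE 0.165), the imprinted non-coding RNA H19 (-2.15, SE 0.163) and the cytokine IL11 (-2.11, SE 0.149) fell furthest. Histone genes had 14 of 20 higher and none lower (adjusted over the list alone, 15 higher and 0 lower), with camera's adjusted p = 4.4e-08 (adjusted p = 0.471 with an estimated correlation). The p53 targets had 10 of 21 lower and none higher (adjusted over the list alone, 0 higher and 11 lower), with adjusted p = 2.1e-07 (adjusted p = 0.456 with an estimated correlation). Mitochondrially encoded genes had 3 of 13 lower (adjusted over the list alone, 0 higher and 3 lower), with adjusted p = 0.00442 (adjusted p = 0.591 with an estimated correlation). After correction for GC content and length, 13 of the 13 were lower, and the median moved from -0.23 to -0.39. Of 27 lists, 11 passed with sh2, 3 higher and 8 lower; 0 passed with an estimated correlation (1 at an unadjusted p under 0.05) and 11 with fry. In all, edgeR called 3074 genes, 1256 higher and 1818 lower. Over coding genes alone, 41.4% of 2740 called genes were higher, against 52.8% of 3792 after correction for GC content and length. The count was 1064 without control 1, 1182 without control 2, 5299 without sh1 1, 5190 without sh1 2, 890 without sh2 1 and 1189 without sh2 2. It was 256 against a fold of 1.5, 5269 when only control and sh2 were fitted, 1774 without genes overlapping an opposite-strand gene and 1885 without genes carrying the 3′ words.

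Both hairpins called 1325 genes in the same direction, 502 higher and 823 lower, where independent calls would give 97.2 and 202.4. Another 61 genes were called in opposite directions, against 280.6 for independent calls. The same-direction genes included HNRNPL, PIK3CB, LDHA, USP18, VAV3, LIMA1 and MMP9. Of these 1325 genes, 41 of the higher and 132 of the lower were also called between the hairpins. Both comparisons used the same control libraries, and in 30 simulations of unchanged groups sharing controls the log2 fold changes correlated at a mean of 0.50 (highest 0.52), against 0.55 observed across 12707 genes (0.50 by rank). The share of genes with the same sign was 67.2% observed and 66.6% on average in the simulations (highest 67.3%), and at most 1 simulated gene was called in the same direction. The covariance was 0.0829 observed against 0.0131 simulated. With the controls divided, so that each hairpin had 1 control library of its own, 370 and 365 genes were called in the same direction for the 2 ways of dividing them. Independent calls would give 8.59 higher and 41.5 lower the first way, against 101 and 269, and 7.13 and 35.1 the second way, against 110 and 255. The log2 fold changes then correlated at 0.46 and 0.48, with 63.0% and 64.4% of genes of the same sign. Over coding genes alone, 37.4% of 1170 same-direction genes were higher, against 50% of 1686 after correction for GC content and length. The count was 384 without control 1, 524 without control 2, 2063 without sh1 2, 480 without sh2 1 and 615 without sh2 2, and 94 against a fold of 1.5, 797 without genes overlapping an opposite-strand gene and 803 without genes carrying the 3′ words.

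**Figure D3:**
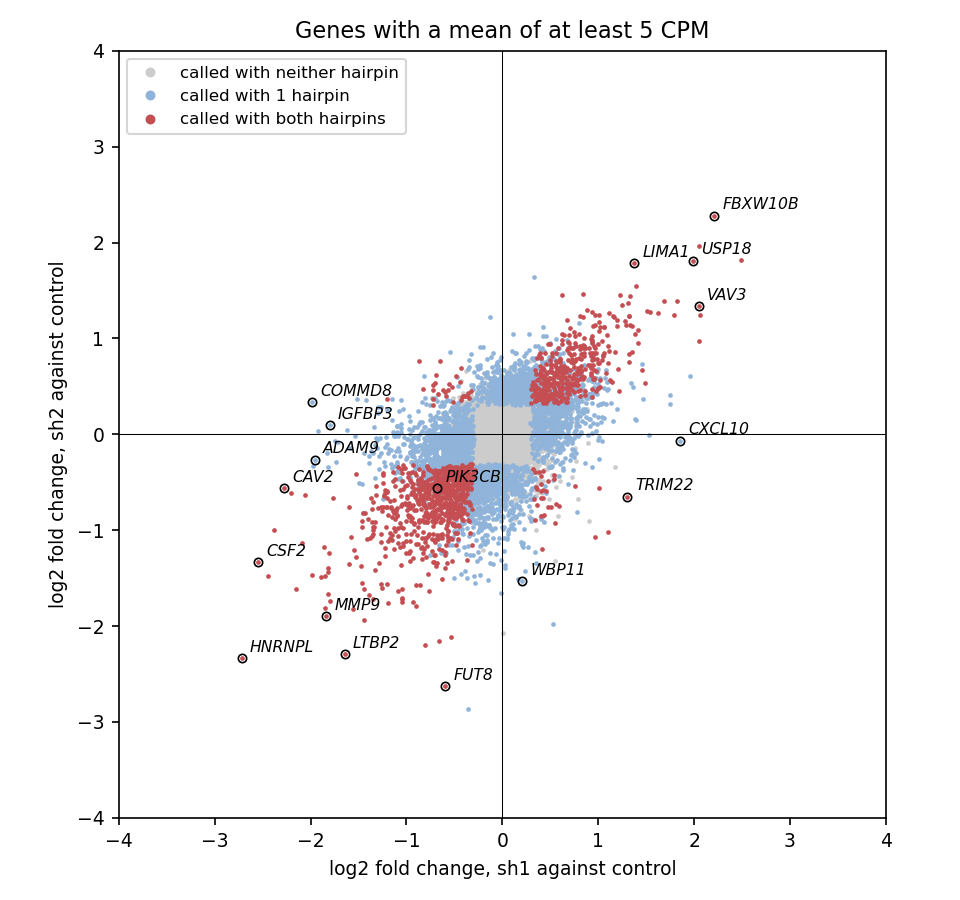
Log2 fold change against control for sh1 (horizontal) and sh2 (vertical) in the 12707 genes with a mean of at least 5 CPM; colour gives whether a gene was called with both, 1 or neither hairpin. HNRNPL, PIK3CB and MMP9 lie low on both axes, FUT8 and WBP11 low on the sh2 axis, and COMMD8, IGFBP3 and ADAM9 low on the sh1 axis.

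The hairpins also differed from each other. This contrast holds what each did beyond their shared target, and also any difference in the depth of HNRNPL knockdown or between libraries. Genes higher in sh1 than in sh2 included TRIM22, an interferon-inducible gene that overlaps an olfactory receptor gene on the same strand, by 1.95 (SE 0.154), the chemokine CXCL10 by 1.92 (SE 0.190), FUT8 by 2.03 (SE 0.139), MARCOL by 2.04 (SE 0.315) and the splicing factor WBP11 by 1.74 (SE 0.106). WBP11 stood at 117 ± 5.73 CPM in the controls, 135 ± 0.932 in sh1 and 40.3 ± 1.98 in sh2 (SD, n = 2). Genes lower in sh1 than in sh2 included COMMD8 at -2.32 (SE 0.143), the insulin-like growth factor binding protein IGFBP3 at -1.89 (SE 0.127), the lipolysis coactivator ABHD5 at -1.89 (SE 0.135), CAV2 at -1.72, the metalloproteinase ADAM9 at -1.69, the annexin ANXA3 at -1.68 and REEP1 at -1.66. C8orf88 (-1.78) and ADPGK-AS1 (2.51) lie opposite a gene with more counts, as does MALT1-AS1 (1.87, SE 0.566). TMEM160 (1.81, SE 0.480) did not pass without sh1 2 (adjusted p = 0.209) or sh2 1 (0.240), or by DESeq2 (0.171), and MALT1-AS1 did not pass without sh1 2 (0.568), sh2 1 (0.314) or sh2 2 (0.0561), by DESeq2 (0.216) or voom (0.119), or at 5 CPM (0.0542). With 1 library left out, MALT1-AS1 ranged from 0.49 to 2.68 and TMEM160 from 0.89 to 2.79. In all, edgeR called 2732 genes between the hairpins, 1270 higher and 1462 lower in sh1. The count was 5065 without sh1 1, 678 without sh2 1 and 934 without sh2 2, and 179 against a fold of 1.5, 1636 without genes overlapping an opposite-strand gene and 1481 without genes carrying the 3′ words.

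Of the gene lists, 5 differed between the hairpins by camera, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 6 by fry. Interferon-stimulated genes were higher in sh1, with 19 of 29 called and none lower (adjusted over the list alone, 21 higher and 0 lower), and camera's adjusted p = 2.7e-08 (adjusted p = 0.403 with an estimated correlation). OAS2 differed by 1.27 (SE 0.122), OAS1 by 0.93 (SE 0.125) and XAF1 by 1.10 (SE 0.149), while USP18 differed by 0.18 (adjusted p = 0.366). The USP18 difference was 0.03 without sh1 1 and 0.31 without sh1 2. The p53 targets were higher in sh1, with 8 of 21 called and 1 lower (adjusted over the list alone, 14 higher and 1 lower), and adjusted p = 4.4e-05 (adjusted p = 0.403 with an estimated correlation). Among them BTG2 differed by 0.88 (SE 0.130) and the pro-apoptotic BBC3 by 0.91 (SE 0.139). Mitochondrially encoded genes were higher in sh1, with 5 of 13 called (adjusted over the list alone, 7 higher and 0 lower), and adjusted p = 0.00173 (adjusted p = 0.728 with an estimated correlation). MT-ND4L, which overlaps MT-ND4 on the same strand, differed by 0.59 (SE 0.110). Histone genes were lower in sh1, with 11 of 20 called and none higher (adjusted over the list alone, 0 higher and 12 lower), and adjusted p = 4.2e-06 (adjusted p = 0.717 with an estimated correlation). H4C14 differed by -1.35 (SE 0.184). Ribosomal protein genes were lower in sh1, with 3 of 31 called (adjusted over the list alone, 0 higher and 10 lower), and adjusted p = 7.8e-05 (adjusted p = 0.728 with an estimated correlation). RPL4 differed by -0.37 (SE 0.102). RPL4 did not pass without control 1 (adjusted p = 0.0531), control 2 (0.0542), sh2 1 (0.149) or sh2 2 (0.208), nor MT-ND4L without sh2 2 (0.0701).

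**Figure D4:**
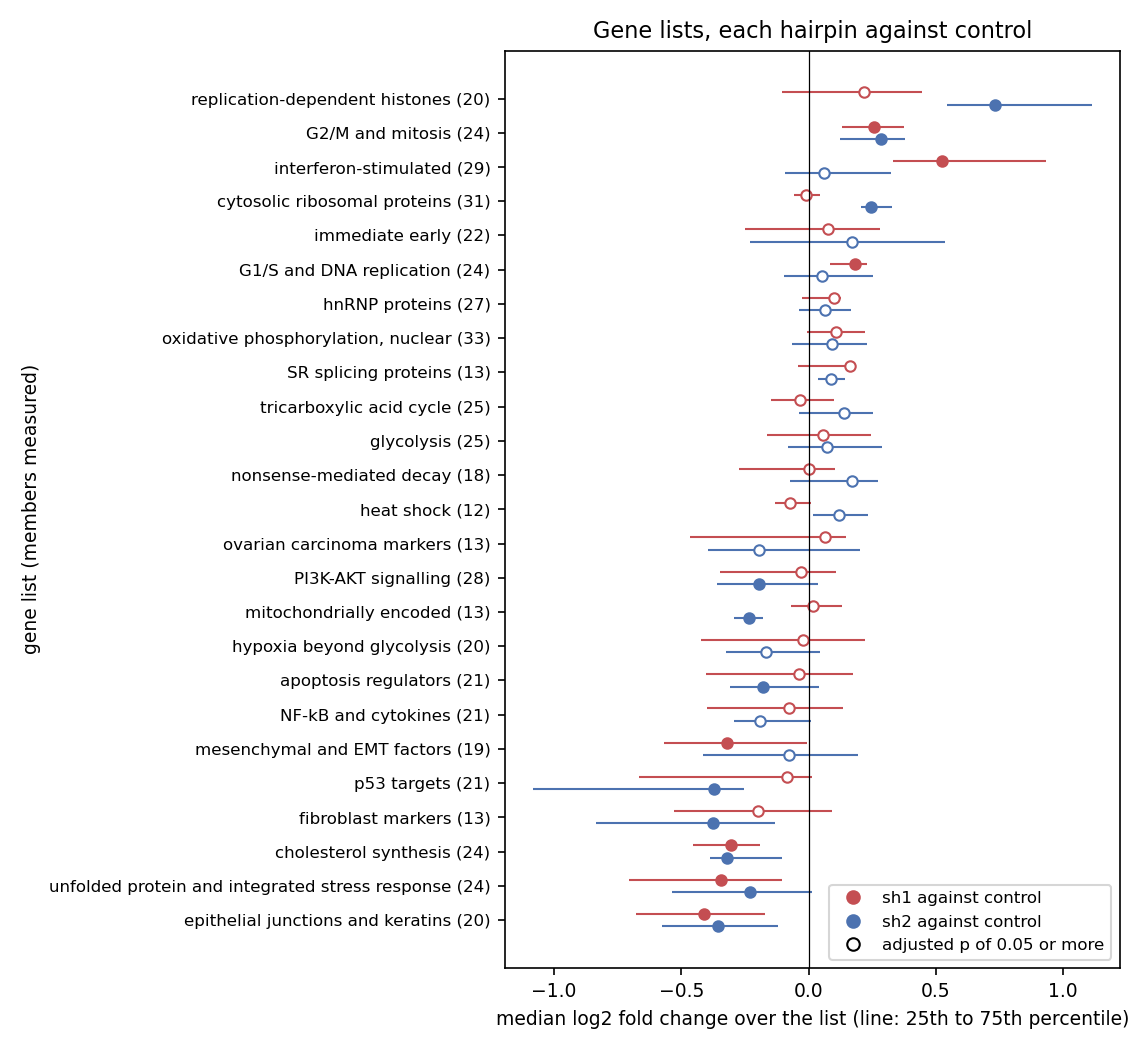
Median log2 fold change of each of 25 gene lists with at least 10 measured members, in sh1 and in sh2 against control, with a line from the 25th to the 75th percentile; filled points passed camera at an adjusted p of 0.05. Interferon-stimulated genes stood at 0.53 in sh1 and 0.06 in sh2, and histone genes at 0.22 and 0.73.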

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

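Of the tests in this part, the ratio of the interferon-stimulated medians of sh2 and sh1, the correction for GC content and length and the count without genes carrying a hairpin's word were chosen only after the result was seen or after the data were seen.

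The hairpins share a target, yet 2732 genes were called between them by a test of that difference. Deeper knockdown by 1 hairpin would move most of these genes the same way and further in sh1. HNRNPL RNA was lower in sh1, though that difference did not pass. By the signs of the estimates, 21.78% did so (interval 20.3% to 23.4%, taking genes as independent). Another 15.9% moved further in sh2, and 62.3% had opposite signs. Opposite signs include genes that barely moved with 1 hairpin, and only 61 tested genes were called in opposite directions. As far as signs can show, these shares argue against deeper knockdown as the whole cause. Bias from GC content or transcript length between libraries was predicted to lower the count when corrected, and it rose from 2540 to 3597 coding genes. A total can rise while some of the first calls are lost. Which calls were kept was not tested, so the total does not exclude such bias for part of the genes. Seed matches remain a candidate explanation for part of the genes. For 2 of 2 hairpins, the 3′ word most strongly tied to lower RNA than with the other hairpin lies in the HNRNPL mRNA. The words lie in CAAATATAC of exon 3 for sh1 and TCAGTTCA of exon 5 for sh2. Chance gives both with probability 0.0174 if all words are equally likely and the 2 picks independent, which was not checked. Genes with the top sh2 word had a median of -0.146 with sh2 and -0.025 with sh1, against 0.019 and -0.030 without it. For the top sh1 word the medians were -0.067 with sh1 and -0.033 with sh2, against -0.017 and 0.011 without it. By these unadjusted medians, the sh1 word went with lower RNA in both hairpins. Of the 2732 genes, 1481 were not found to carry a word of either hairpin. A 3′ region was searched for 1075 of these and not for 406. The words, chosen from these same differences, were found in 5444 of 17888 tested genes (30.4%). Of the tested genes, 12998 had a 3′ region that was searched, as did 2326 of the 2732. Comparing the shares is no test, other causes stay open, and none beyond those above was tested.

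Interferon-stimulated genes stood higher in sh1 than in sh2 by a list median of 0.48, which did not pass with an estimated correlation (adjusted p = 0.403). If the list followed HNRNPL in proportion, deeper knockdown in sh1 would give sh2 a median at least 0.5 times as large. The log2 fall of HNRNPL in sh2 was 0.858 of that in sh1. The ratio of medians was 0.1169 (interval -0.15 to 0.42), below that prediction. The interval treats list members as independent and leaves out the spread between libraries. It therefore cannot exclude deeper knockdown. GC content or length bias is argued against for this list, since the median difference was 0.4984 after correction and 0.5006 before. A response to the hairpin RNA itself, or to its other targets, may contribute and was not tested. The list had 27 of 29 members higher in sh1.

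The other differences between the hairpins passed the same test and are given as sh1 minus sh2. Genes also moved by the average contrast differed by 0.67 (MRPS30-DT), 0.71 (VAV3), 0.82 (TMEM161B-DT), -0.41 (LIMA1), 0.55 (LUCAT1), 0.65 (LTBP2), -0.97 (CHAC1) and -1.22 (CSF2). Of these differences, calls were lost for MRPS30-DT (adjusted p = 0.0526) without control 1, MRPS30-DT (0.0757), TMEM161B-DT (0.158), LUCAT1 (0.111), LTBP2 (0.146), CHAC1 (0.0963) and CSF2 (0.0996) without sh1 2, MRPS30-DT (0.178), TMEM161B-DT (0.105), LIMA1 (0.180), LUCAT1 (0.187), LTBP2 (0.179), CHAC1 (0.0736) and CSF2 (0.124) without sh2 1, and MRPS30-DT (0.192), TMEM161B-DT (0.190), LIMA1 (0.0659), LUCAT1 (0.101), LTBP2 (0.102), CHAC1 (0.223) and CSF2 (0.0902) without sh2 2. DESeq2 did not call MRPS30-DT (0.150) or CHAC1 (0.0644), nor voom CHAC1 (0.0597). Without sh1 2 the differences were 0.49 (TMEM161B-DT), 0.30 (LUCAT1), 0.39 (LTBP2) and -0.70 (CSF2), and without sh1 1 that of CSF2 was -2.05, which passed. Genes named for a single hairpin differed by -1.72 (CAV2), -1.31 (PSG4), 2.03 (FUT8), 1.49 (H19) and 1.57 (IL11). Higher in sh1 were ADPGK-AS1 (2.51), MARCOL (2.04), TRIM22 (1.95), CXCL10 (1.92), WBP11 (1.74), MALT1-AS1 (1.87) and TMEM160 (1.81). MALT1-AS1 ranged from 0.49 to 2.68 and TMEM160 from 0.89 to 2.79 with 1 library left out, and neither passed in all of these fits. Lower in sh1 were COMMD8 (-2.32), IGFBP3 (-1.89), ABHD5 (-1.89), C8orf88 (-1.78), ADAM9 (-1.69), ANXA3 (-1.68) and REEP1 (-1.66). The words most tied to lower RNA than with the other hairpin were AAATATA for sh1 (Bonferroni-adjusted p = 2.5e-38) and TCAGTTC for sh2 (3.6e-59). They came from regression of the difference between hairpins over 16147 words and 10723 genes. The scan found 10 of 10 words planted with an effect of -0.3, larger than those of AAATATA (-0.13) and TCAGTTC (0.19), so recovery at the observed size was not tested, and it made a call in 1 of 10 scans of shuffled values. The lists also differed, with medians of 0.40 for p53 targets, 0.26 for mitochondrially encoded genes, -0.26 for ribosomal proteins and -0.50 for histones. None of these 4 passed with an estimated correlation, with adjusted p of 0.403, 0.728, 0.728 and 0.717 in that order.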

How the results depend on the processing

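The fits without genes overlapping an opposite-strand gene, with a correction for GC content and length and with divided controls, and the counts without genes carrying a hairpin's words were added only after the data were seen. No called gene or list median changed sign under the alternatives run for it. Values that were not called and changed sign were the average medians of heat shock genes (0.03, against -0.01 without control 2 and just under 0 without sh2 1) and immediate early genes (0.11, against -0.02 without control 2), PIK3CB between hairpins (-0.11, against 0.05 without sh2 1) and PIK3R1 with sh1 (0.12, against -0.02 without control 2 and -0.03 without sh1 2). After correction for GC content and length, medians changed sign with sh1 for mitochondrially encoded (0.04 to -0.20), ribosomal (0.01 to -0.07) and hypoxia genes (0.0020 to -0.02), with sh2 for endothelial markers (-0.17 to 0.03), and between hairpins for glycolysis (0.02 to -0.03), PI3K-AKT (0.01 to -0.04) and nuclear oxidative phosphorylation genes (-0.01 to 0.02), and the share of sh2 calls that were higher went from 41.4% to 52.8%. Of the 10 lists called on average, 0 passed with an estimated correlation. HNRNPL kept its call under all 17 alternatives of the average contrast; its average log2 fold change ranged from -2.62 to -2.46 with 1 library left out. Tested against a fold of 1.5, the counts were 246 (average), 344 (sh1), 256 (sh2), 179 (between hairpins) and 94 (same direction), since small changes no longer count, and PIK3CB (-0.62) gave adjusted p = 1. With the 4 knockdown libraries as 1 group the average gave 758, since differences between hairpins then add to the spread. With only control and sh2 fitted sh2 gave 5269, and with only control and sh1 fitted sh1 gave 2481. The sh1 pair, the least alike, adds to the shared spread of the 3 groups and not to that of control and sh2 alone. Other causes were not tested. Without genes overlapping an opposite-strand gene the counts were 1993, 2063, 1774, 1636 and 797, and without genes carrying a hairpin's words 2059, 2011, 1885, 1481 and 803, with fewer genes tested or counted. Fry gave the glycolysis list (median 0.039) adjusted p = 0.0461 against 0.339 by camera; the range over its alternatives was 0.0461 to 0.705. With 1 library left out the counts ranged from 1037 to 5249 (average), 1210 to 4940 (sh1), 890 to 5299 (sh2), 678 to 5065 (between hairpins) and 384 to 2063 (same direction), where the group with 1 library is assumed to vary like the others; the cause was not tested. PIK3CB ranged from -0.71 to -0.56 with adjusted p up to 0.0356. With the controls divided between the hairpins, 370 and 365 genes were called in the same direction, with 1 control library for each hairpin in place of 2. DESeq2 called 2448, 2396, 2205, 2236 and 912 genes and limma-voom 3382, 3319, 3043, 2666 and 1307. Of 60 gene and contrast pairs given by the naming rule besides HNRNPL and PIK3CB on average, 57 kept their call under each of up to 13 alternatives, and HNRNPLL, MALT1-AS1 and TMEM160 did not. Of 91 further pairs called and printed, chosen for these fits after the data were seen, 24 kept their call in all, 31 lost it only against a fold of 1.5, and 36 lost it in another fit, on average ATP5PO, BCL2L2, BIRC5, CDC25B, CDC45, CLSPN, COL1A1, CXCL10, CXCL2, ESAM, H2BC5, HNRNPR, HSPA1B, MDH1, MSLN, NDUFA1, PDK1, PTBP1, RALY, SMG6, TPI1 and VEGFA, with sh1 CDC45, CLSPN and HNRNPLL, with sh2 PFKM and PIK3CB, and between hairpins CHAC1, CSF2, LIMA1, LTBP2, LUCAT1, MRPS30-DT, MT-ND4L, RPL4 and TMEM161B-DT. Of 6 printed and not called, HNRNPL between hairpins, HNRNPLL with sh2 and MT-CO3 on average passed in another fit. A count of 0 leaves levels up to 0.244 CPM open at this depth. The smallest difference that could be detected between groups depends on level and spread and was not tested for each gene.

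With the replicate number as a block, 3065, 3029, 2724, 2410 and 1152 genes were called, and MRPS30-DT between hairpins had adjusted p = 0.0541. Deviations of libraries with the same number correlated at 0.00540, 0.0209 and -0.0462 across genes. These low correlations gave no sign that the numbers pair the libraries, but cannot exclude pairing that affects only part of the genes.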

Other observations

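Chosen only after the result was seen were the interval of the SD of the BEST1 to FTH1 ratio, the condition that it lie below the median of similar genes, and the members of lists named below beyond the 4 with the smallest p.

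Among metabolic lists, the tricarboxylic acid cycle had 2 of 25 higher and 2 lower (adjusted over the list alone, 1 higher and 2 lower), with glutamate dehydrogenase GLUD1 at -0.93 (SE 0.0841) and isocitrate dehydrogenase IDH2 at -0.94 (SE 0.112) against MDH1 at 0.38 (SE 0.0858) (adjusted p = 0.694, or 0.874 with an estimated correlation as the adjusted p). The list's median was 0.05 and its mean -0.01. That median was 0.0016 without control 2 and 0.06 without control 1. Nuclear oxidative phosphorylation had 4 of 33 higher and 1 lower (adjusted over the list alone, 4 higher and 1 lower), with ATP5PO at 0.66 (SE 0.176) and NDUFA1 at -0.45 (SE 0.123) (adjusted p = 0.211, or 0.737 with an estimated correlation as the adjusted p). Hypoxia genes had 2 of 20 higher and 5 lower (adjusted over the list alone, 2 higher and 5 lower), with ADM at 0.60 (SE 0.102), KDM3A at 0.56 and the growth factor VEGFA at -0.49 (SE 0.0865) (adjusted p = 0.358, or 0.696 with an estimated correlation as the adjusted p). Mitochondrially encoded genes had 0 of 13 higher and 0 lower (adjusted over the list alone, 0 higher and 0 lower), with MT-CO3 at -0.22 (SE 0.0833) (adjusted p = 0.147, or 0.696 with an estimated correlation as the adjusted p), and after GC content and length correction the median moved from -0.12 to -0.30 with 10 lower. ATP5PO and MT-CO3 each overlap a coding gene on the same strand. Heat shock genes had 1 of 12 higher and 0 lower (adjusted over the list alone, 1 higher and 0 lower), with HSPA1B at 0.58 (SE 0.157) (adjusted p = 0.439, or 0.794 with an estimated correlation as the adjusted p). DNA replication genes had 3 of 24 higher and 0 lower (adjusted over the list alone, 3 higher and 0 lower), with CLSPN at 0.42 (SE 0.0991) and CDC45 at 0.45 (SE 0.111) (adjusted p = 0.0743, or 0.696 with an estimated correlation as the adjusted p). DNA replication genes passed at a filter of 5 CPM (adjusted p = 0.0351) and without sh1 2 (0.0245), nuclear oxidative phosphorylation genes without sh1 2 (0.0161), and mitochondrially encoded genes with no low-count filter (0.0358) and without sh1 1 (0.0433). Calls of members were lost for MDH1 (adjusted p = 0.109), ATP5PO (0.112), NDUFA1 (0.150), VEGFA (0.0519), HSPA1B (0.0697), CLSPN (0.0912) and CDC45 (0.227) without control 1, MDH1 (0.124), ATP5PO (0.144), NDUFA1 (0.132), HSPA1B (0.208) and CLSPN (0.148) without control 2, ATP5PO (0.0521), NDUFA1 (0.0932), HSPA1B (0.0931) and CLSPN (0.0563) without sh2 1, and ATP5PO (0.0559) and CDC45 (0.0561) without sh2 2, and ATP5PO by DESeq2 (0.0664). MT-CO3 passed without sh1 1 (adjusted p = 0.00184) or sh1 2 (0.00310), by DESeq2 (0.0314) and with no low-count filter (0.0174).

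Among regulatory lists, hnRNP proteins had 4 of 27 higher and 2 lower (adjusted over the list alone, 4 higher and 2 lower), with PTBP1 at -0.35 (SE 0.0829), HNRNPR at 0.31 (SE 0.0862) and RALY at 0.32 (SE 0.0878) besides HNRNPL and HNRNPLL (adjusted p = 0.339, or 0.737 with an estimated correlation as the adjusted p). The median of this list was 0.07 and its mean -0.02. That median was 0.04 without sh1 1 and 0.09 without control 1. SR splicing proteins had 0 of 13 higher and 1 lower (adjusted over the list alone, 0 higher and 1 lower), with SRSF9 at -1.01 (SE 0.0836) (adjusted p = 0.439, or 0.705 with an estimated correlation as the adjusted p). Nonsense-mediated decay genes had 0 of 18 higher and 1 lower (adjusted over the list alone, 0 higher and 1 lower), with SMG6 at -0.39 (SE 0.104) (adjusted p = 0.748, or 0.794 with an estimated correlation as the adjusted p). Apoptosis regulators had 1 of 21 higher and 6 lower (adjusted over the list alone, 1 higher and 8 lower), with the anti-apoptotic BCL2L1 at -1.02 (SE 0.0815) and BCL2L2 at -0.58 (SE 0.105) and the pro-apoptotic PMAIP1 at -0.53 (SE 0.0852) (adjusted p = 0.0831, or 0.371 with an estimated correlation as the adjusted p). Immediate early genes had 5 of 22 higher and 5 lower (adjusted over the list alone, 8 higher and 5 lower), with FOS at 0.87 (SE 0.108) and NR4A1 at 0.83 (SE 0.114) against DUSP6 at -0.96 (SE 0.120) and KLF6 at -0.51 (SE 0.0809) (adjusted p = 0.439, or 0.737 with an estimated correlation as the adjusted p). NF-kB and cytokine genes had 3 of 21 higher and 4 lower (adjusted over the list alone, 4 higher and 10 lower), with CSF2 at -1.94 (SE 0.225) against IL6 at 0.73 (SE 0.0935), CXCL10 at 0.89 (SE 0.174) and CXCL2 at 0.71 (SE 0.139) (adjusted p = 0.339, or 0.705 with an estimated correlation as the adjusted p). Apoptosis regulators passed with fry (adjusted p = 0.0148) and with no low-count filter (0.0206). Calls of members were lost for PTBP1 (adjusted p = 0.202), HNRNPR (0.240), RALY (0.210), SMG6 (0.206) and CXCL2 (0.0617) without control 1, PTBP1 (0.0719), HNRNPR (0.169), RALY (0.203), SMG6 (0.107), BCL2L2 (0.0685) and CXCL10 (0.0646) without control 2, HNRNPR (0.0977), RALY (0.0722) and SMG6 (0.0713) without sh2 1, and PTBP1 (0.0566), HNRNPR (0.0844) and RALY (0.106) without sh2 2. CXCL10 stood at 1.34 without control 1 and 0.55 without control 2. BCL2L2 overlaps a coding gene on the same strand.

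Markers of other cell types gave these values. Ovarian carcinoma markers had 0 of 13 higher and 4 lower (adjusted over the list alone, 0 higher and 4 lower), with CLDN4 at -1.01 (SE 0.116) and MSLN at -0.46 (SE 0.108) (adjusted p = 0.439, or 0.696 with an estimated correlation as the adjusted p). Leukocyte markers had 0 of 2 higher and 0 lower (adjusted over the list alone, 0 higher and 0 lower), in a list of 2 measured members (adjusted p = 0.439, or 0.719 with an estimated correlation as the adjusted p). Endothelial markers had 0 of 3 higher and 1 lower (adjusted over the list alone, 0 higher and 1 lower), with ESAM at -0.48 (SE 0.112) (adjusted p = 0.339, or 0.696 with an estimated correlation as the adjusted p). Fry called ovarian carcinoma markers (adjusted p = 0.0168) and endothelial markers (0.0211). Calls of members were lost for MSLN (adjusted p = 0.119) and ESAM (0.199) without control 1, MSLN (0.0674) without control 2, and MSLN (0.0563) without sh2 1. In the controls, the leukocyte gene PTPRC had 0.148 CPM and the endothelial PECAM1 0.334. The keratins KRT7, KRT8 and KRT18 had 1576, 2649.7 and 1267 CPM, FOLR1 1358 and MSLN 206, PAX8 9.95, MUC16 24.0 and EPCAM 5.97. CDH1 had 0.0742, GRHL2 0.0750 and WFDC2 0.0734 CPM, all under the limit that 3 counts set, and WT1, SOX17 and ESRP1 had 0 in both controls. The collagens COL5A1, COL1A1 and COL1A2 had 3830.3, 38.1 and 0.149 CPM. Other fibroblast markers also lay at both ends. S100A4, which overlaps S100A3 on the same strand, had 914 CPM, FBN1 225, COL6A1 127, FAP 33.6 and DCN 16.0. PDGFRA had 0.112 CPM, THY1 0.0742, and POSTN and DPT 0. The labels give the line as OVCAR3 and the cell type as fibroblasts. These values are given without deciding between the labels, and whether either label is right stays open for all results here.

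BEST1, which overlaps FTH1 over 1267 bases on the opposite strand, ranked 4 among all genes by counts, at 77.8% to 95.1% of FTH1. A candidate explanation is that reads carrying no strand were counted by strand. Counts per base were compared over 182 pairs of opposite-strand genes that overlap by at least 300 bases. The rarer partner had a median of 2.008 times the counts per overlapping base that the other had per exonic base (interval 1.69 to 2.31). For reads kept by strand, a median under 0.1 was predicted beforehand. All counts of the rarer partner enter the ratio, also those from outside the overlap. Reads kept by strand can therefore give a high ratio too, and the median cannot decide between these cases. The ratio lay within 3-fold of 1 in 56.0% of pairs and under 0.1 in 11%, so the explanation does not cover every pair. BEST1 transcribed at that level on its own is argued against: the log2 ratio of BEST1 to FTH1 had an SD of 0.1009 over the 6 libraries, against a median of 0.407 for 27 genes of similar abundance, the lowest at 0.247. The SD lay narrowly under the bound set beforehand of 0.102, and its interval of 0.0630 to 0.247 reaches past that bound and stays below the median. Of 17888 tested genes, 4171 have a more counted partner on the opposite strand, as do 590 of the 3420 called on average.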
